A study of Mus musculus with 6 samples.

How the data were processed

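The series holds 6 one-colour arrays of in vitro derived mouse germ cells that express a tagged DAZL protein. They fall into 3 groups of 2 replicates, as the labels name them: total input RNA, RNA recovered with an antibody to PABP1, and RNA recovered with an antibody to GFP. Per the labels, RNA was recovered after ultraviolet crosslinking, treated with proteinase K, extracted, and labelled with Cy3 by the array maker's one-colour protocol.

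Per the file headers, the deposited scanner files hold spot intensity and the processed signal that Agilent Feature Extraction 9.1.3.1 computed by subtracting background from the intensity of each spot. The deposited files also flag spots that are well above background, saturated or outliers, and identify the slide. The authors also deposited a table whose columns are group means and standard errors of signal, which its header describes as scaled to the median of each array, and a quality score. The score in the deposited table ran from -0.294 to 1.00 and entered no test, nor did the standard errors. No test was run on the authors' values, and they were not rebuilt from the scanner values.

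Control spots and outlier spots were left out, and the log2 processed signals of the spots of a probe were averaged and divided by the array's 75th percentile, that is, their log2 values were subtracted. Gene names came from the files and, through accessions, from a RefSeq gene table of assembly GRCm38.p6, used for names alone: 22951 of 41174 probes were named through an accession and 1098 through a name shared with such a probe. Of 41 names that a spreadsheet had turned into dates, 28 were recovered through the accession. A probe was kept if it was well above background on both arrays of at least 1 group, which left 21051 probes. Each gene was read by its kept probe with the highest mean signal over all 6 arrays, chosen without regard to group, giving 14991 genes; 15578 probes were well above background on all 6 arrays.

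The comparisons were GFP IP against input, PABP1 IP against input and GFP IP against PABP1 IP. Each used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on all 6 arrays with group as the only factor and 3 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested in a comparison and a threshold of 0.05. Values after ± are standard errors from limma, with 2 arrays per group. Where the dimmer group had no array well above background, the fold is given as at least the ratio to the larger of that group's signal and the lowest signal well above background on the array. No fold is given where both groups were below background. Overlaps between comparisons that share arrays were set beside the overlap of independent lists and beside 50 simulations of unchanged groups.

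The 25 gene lists were fixed before the data were examined, and 24 had a measured member. They cover reported DAZL targets, 6 mRNAs taken from general knowledge to be targets named by the study (a source not checked here), pluripotency, primordial germ cells, meiosis, Polycomb, apoptosis, cytosolic and mitochondrial ribosomal proteins, translation factors, oxidative phosphorylation, replication-dependent histones, nuclear or regulatory non-coding RNAs, nuclear and cytoplasmic RNA-binding proteins, cell cycle, secreted and extracellular matrix, heat shock and stress, and markers of visceral endoderm, cardiac and smooth muscle, neural, fibroblast, endothelial and blood, and trophoblast cells. The list of mitochondrially encoded transcripts had no measured member. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists of a comparison, with an estimated correlation and fry beside it; no camera call held with an estimated correlation. That loss does not measure correlation between genes alone. It also met lists whose estimated correlation lay below the preset value, such as Polycomb (-0.021). List positions are medians of log2 differences minus the median of all genes, which a constant scaling cannot move.

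Genes named in the text follow a rule fixed before the data were examined. It takes, per comparison, the 10 largest differences in each direction among genes past the threshold whose arrays of the 2 groups do not overlap, that are well above background in the higher group and that have an official-looking symbol. It adds up to 4 members per list with the largest differences past the threshold, of which the text gives some, and a fixed set that includes Dazl, Pabpc1, Ddx4, Sycp3, Tex19.1, Suz12, Sall4, Sox2, Casp2, Casp9, Pou5f1 and Nanog.

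The analysis was tested on simulated data with 14991 genes. In GFP IP against input 3 of 100 genes changed by a log2 difference of 1 and 67 of 100 changed by 2 were recovered, with 5 false calls. In GFP IP against PABP1 IP 2 of 100 and 68 of 100 were recovered, with 2 false calls. In PABP1 IP against input, where no gene was changed, there were 0. Far fewer genes were changed here than the 8301 that passed in GFP IP against input in the data. The adjusted threshold is stricter where fewer genes differ, so these shares do not give the recovery in the data.

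Alternatives were normexp background correction with an offset of 50, scaling to the median of kept probes, quantile normalization, cyclic loess, no filter on dim probes, a filter for probes well above background on all 6 arrays, a floor at the lowest detected signal, every kept probe on its own, the mean of a gene's probes, and saturated probes left out, which removed 0. The variance model (trend and robust), a fit of the 2 compared groups alone, a replicate block, a slide block, treat with a minimum log2 difference of 0.5, and each array left out in turn were also run. Chosen after seeing the data were scaling to the median of all probes, scaling to the spike-in controls, the fit within slide 1, a crossed replicate block for the 2 IPs, and the slide block with an estimated correlation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.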

Results

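RNA was measured on 6 one-colour whole-genome mouse arrays in germ cells grown from mouse embryonic stem cells after 12 days of differentiation. The cells carried DAZL, an RNA-binding protein of the germ line, fused to GFP and a V5 tag. After ultraviolet crosslinking of protein to RNA, RNA was recovered with an antibody to GFP (2 arrays) or to the poly(A)-binding protein PABP1 (2 arrays). Total RNA taken before the immunoprecipitation (IP), called input, was hybridised to 2 arrays. Each array read 43379 spots for 41174 probes, of which 41.5% to 52.6% of spots were well above background and 0 were saturated. The 75th percentile signal was 63.6 and 75.4 on the input arrays, 105 and 146 on the PABP1 arrays, and 158 and 163 on the GFP arrays. Both input arrays, PABP1 IP replicate 1 and GFP IP replicate 2 shared a slide (slide 1), while GFP IP replicate 1 and PABP1 IP replicate 2 shared another (slide 2). Replicates correlated at 0.992 (input), 0.982 (PABP1 IP) and 0.981 (GFP IP) across genes, and arrays of different groups at 0.872 to 0.934, with genes not being independent replicates. The number of arrays limits the precision, and the labels do not say that replicates come from separate cultures, so the p-values measure only the spread between these arrays.

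The GFP IP was compared with input to ask which transcripts came down with tagged DAZL. The Dazl mRNA was 13.8-fold higher in the GFP IP (log2 difference 3.78 ± 0.27 SE, n = 2 arrays per group, adjusted p = 0.00148), and a dimmer Dazl probe gave 2.44. Dazl encodes the tagged protein itself, so its mRNA may behave unlike other targets, which was not tested. Tex19.1, a germ cell gene of transposon control, was 9.37-fold higher (3.23 ± 0.19, adjusted p = 0.00148). A list of 6 mRNAs was fixed from general knowledge before the data were examined. They were taken to be targets named by the study of these samples, a source that was not checked. Of these, 6 were higher and 0 were lower, among them the pluripotency factors Sox2 (2.11 ± 0.16, adjusted p = 0.00155) and Sall4 (2.02 ± 0.21, adjusted p = 0.00231). Also among them were the Polycomb subunit Suz12 (2.07 ± 0.25, adjusted p = 0.00276, with another probe at 1.38) and the caspases Casp2 (1.45 ± 0.16, adjusted p = 0.0024) and Casp9 (1.63 ± 0.23, adjusted p = 0.00392). If the study drew these targets from the same samples, the count, 6 also when adjusted over the list alone, is not independent evidence. Its median lay 2.57 above that of all genes (camera adjusted p = 4.84e-05, adjusted p = 0.157 with an estimated correlation). Another Sall4 probe gave -0.19, and the mean of the Sall4 probes was 0.91 with adjusted p = 0.0655.

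**Figure D1:**
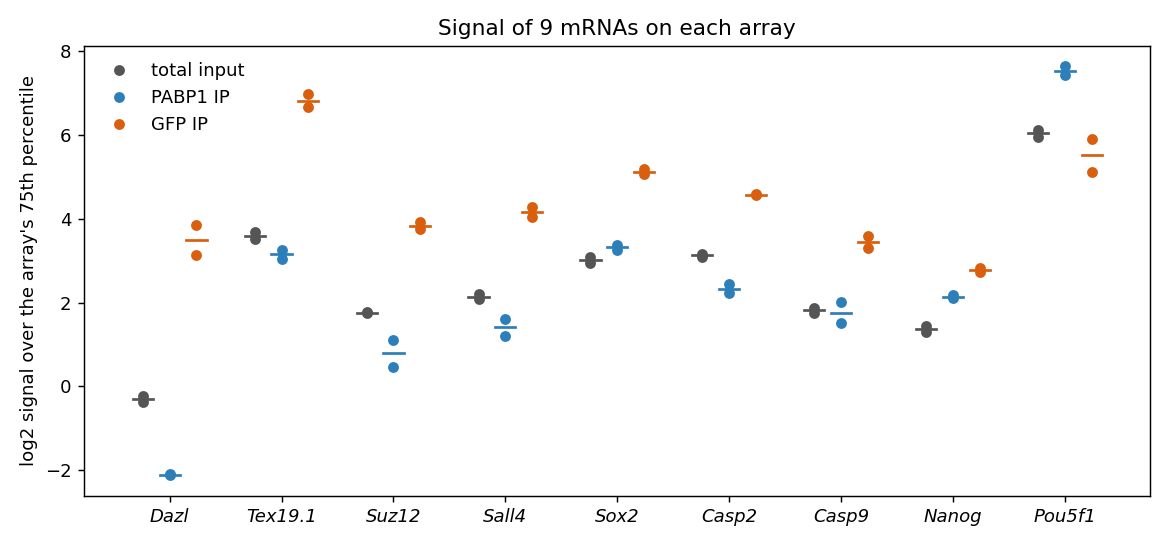
Each point is an array, plotted as log2 signal over that array's 75th percentile for 9 mRNAs, with a bar at the mean of the 2 arrays of each group (total input, PABP1 IP, GFP IP). Both GFP IP points lie above all 4 control points for each mRNA except Pou5f1, whose GFP IP points lie below the input points.

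Of 8 measured mRNAs on a list of reported DAZL targets, 4 were higher in the GFP IP than in input, 1 was lower and 3 did not pass, and 5 were higher and 1 lower when adjusted over the list alone. The list held Tex19.1 and also Dazl, which encodes the tagged protein. Sdad1 was at 1.94 ± 0.31 (adjusted p = 0.00544) and the spermatogenesis gene Tex14 lower at -1.27 ± 0.16 (adjusted p = 0.0031; 0.096 with the median of all probes and 0.888 with spike-in scaling). Another Sdad1 probe gave -1.46, and the mean of the Sdad1 probes was 0.24 (adjusted p = 0.409). The list's median lay 1.34 above that of all genes (camera adjusted p = 0.022, adjusted p = 0.427 with an estimated correlation), and its call was lost after quantile normalization (adjusted p = 0.0508) and with spike-in scaling (adjusted p = 0.0752). The reported targets Ddx4 and Sycp3 were not well above background on both arrays of any group and were not tested. Nanog was higher (1.41 ± 0.15, adjusted p = 0.00242), while Pou5f1 (-0.52 ± 0.29, adjusted p = 0.18) and Pabpc1, the mRNA of PABP1 itself (-0.87 ± 0.69, adjusted p = 0.318), did not pass. With the slide as a block Pou5f1 did pass (-0.77, adjusted p = 0.0307), as it did within slide 1 (-0.92, adjusted p = 0.0214) and without GFP IP replicate 1 (adjusted p = 0.0364).

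Among genes with an official-looking symbol, the largest increase over input was that of Dck, which encodes deoxycytidine kinase (4.93 ± 0.26, 30.5-fold). Among those measured in both groups, and leaving out Ccdc43, given below, next came Cd38 (4.30 ± 0.17), Cggbp1 (4.15 ± 0.23), Coq10b (4.11 ± 0.37), Sgpp1 (4.08 ± 0.25), Cdyl (4.05 ± 0.43) and Dr1 (3.99 ± 0.21). Dusp14 was at least 22.7-fold higher (adjusted p = 0.00148) and the ubiquitin ligase gene Siah1a at least 5.33-fold higher (adjusted p = 0.00177), since input was not well above background. The nuclear non-coding RNA Malat1 was far below input (-5.07 ± 0.47, adjusted p = 0.00193). Gdap10 (-3.85 ± 0.32), the nuclear pore gene Tpr (-3.85 ± 0.38), Nemf (-3.84 ± 0.39) and Mink1 (-3.65 ± 0.55) were also lower. Hectd2 was at least 6.90-fold lower (adjusted p = 0.00148) and Ovgp1 at least 7.57-fold lower (adjusted p = 0.00785). Other probes gave smaller values for Dck (2.14 and 3.21), Cd38 (0.77), Cdyl (2.37), Dr1 (2.42), Tpr (-0.58), Nemf (-2.02), Mink1 (-0.65), Khsrp (-1.14), Malat1 (-4.10 and -3.86) and Dusp14 (3.71, against 4.51). The calls of 4 further genes were lost without a single array. Ccdc43 (4.12 ± 1.16, adjusted p = 0.0315) gave 2.79, 3.76 and 4.47 (adjusted p = 0.108, 0.127 and 0.0829) without GFP IP replicate 1, input replicate 1 and input replicate 2, and another Ccdc43 probe gave -0.49. Olfr1497, at least 6.67-fold lower (adjusted p = 0.0301), had adjusted p = 0.115, 0.0991 and 0.107 without the same 3 arrays. With a replicate block Ccdc43 and Olfr1497 had adjusted p = 0.0744 and 0.0725, and with a minimum log2 difference of 0.5 they had 0.0542 and 0.0537. Khsrp (-3.59 ± 0.76, adjusted p = 0.0132) had adjusted p = 0.0651 and 0.0558 without input replicates 1 and 2, and Golgb1 (-3.79 ± 0.79, adjusted p = 0.0125) had 0.0622 without input replicate 2. With spike-in scaling Olfr1497, Khsrp and Golgb1 had adjusted p = 0.115, 0.0568 and 0.0546. Other Golgb1 probes gave -2.51 and -5.18.

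Polycomb genes, which encode a chromatin repressor system, lay 1.33 above all genes by their median in the GFP IP against input. Of 30 measured, 16 were higher, 2 lower and 12 did not pass (17 higher and 2 lower adjusted over the list alone), with camera adjusted p = 8.18e-06 and adjusted p = 0.138 with an estimated correlation. Pcgf5 was 9.24-fold higher (3.21 ± 0.15) and Kdm2b 5.41-fold higher (2.44 ± 0.28). Genes for cytoplasmic RNA-binding proteins lay 1.08 above all genes, with 22 of 50 higher, 6 lower and 22 not past (24 and 6 adjusted over the list alone). Elavl1 (2.95 ± 0.20, with other probes at 1.22 and 1.69), Fmr1 (8.01-fold, SE 0.29 on the log2 scale, with another probe at 1.94) and Elavl2 (2.21 ± 0.17) were among them, with camera adjusted p = 4.33e-05 for the list and adjusted p = 0.138 with an estimated correlation. Genes for nuclear RNA-binding and splicing proteins moved both ways, 19 of 42 higher, 12 lower and 11 not past, as over the list alone. Hnrnpc (2.50 ± 0.15) and Srsf6 (2.41 ± 0.39, with another probe at 1.51) were higher and Luc7l3 (-2.54 ± 0.25) lower, with the list's median 1.02 above all genes (camera adjusted p = 0.00703, adjusted p = 0.427 with an estimated correlation, and 0.0585 with spike-in scaling, where the call was lost). Of 30 pluripotency genes 12 were higher, 5 lower and 13 not past, again as over the list alone, with Mycn 6.08-fold higher (2.60 ± 0.20). Their median lay 0.80 above all genes (camera adjusted p = 0.00368, adjusted p = 0.478 with an estimated correlation). Of 22 primordial germ cell genes 10 were higher, 9 lower and 3 not past (11 and 9 over the list alone), and the list did not pass (camera adjusted p = 0.0765, but 0.0494 without GFP IP replicate 2, 0.00197 with no filter on dim probes and 0.0408 with fry), while its member Kit, a receptor of germ cell survival, was 7.82-fold higher (2.97 ± 0.24).

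Genes of oxidative phosphorylation lay -0.60 from the median of all genes in the GFP IP against input. Of 84 measured, 63 were lower, 2 higher and 19 did not pass (65 and 2 adjusted over the list alone), with camera adjusted p = 8.18e-06 and adjusted p = 0.525 with an estimated correlation. Ndufb2 (-2.21 ± 0.21) and Ndufa5 (-2.01 ± 0.16), subunits of complex I, were examples. Replication-dependent histone genes lay -1.16 from all genes, with 24 of 30 lower, 1 higher and 5 not past, as over the list alone (camera adjusted p = 0.00145, adjusted p = 0.525 with an estimated correlation). H3c1 (-2.20 ± 0.26) and H2bc1 (4.01-fold lower, SE 0.23 on the log2 scale) were among the lower ones. Mitochondrial ribosomal protein genes lay -0.33 from all genes, or 0.15 with normexp background and 0.22 with no filter on dim probes, with 48 of 78 lower, 5 higher and 25 not past (50 and 5 over the list alone). Mrpl41 (-1.79 ± 0.19) and Mrps34 (-1.67 ± 0.23) were lower, with camera adjusted p = 0.00158 for the list and adjusted p = 0.672 with an estimated correlation. The call of the list was lost with normexp background (0.931), cyclic loess (0.0569), no filter on dim probes (0.107) and spike-in scaling (0.338). Spike-in scaling also lost the calls of Mrps34 (-0.44, adjusted p = 0.103) and H2bc1 (-0.77, adjusted p = 0.0502). Cytosolic ribosomal protein genes lay -0.62 from all genes, or 0.09 after quantile normalization, with 44 of 84 lower, 0 higher and 40 not past (33 lower over the list alone, camera adjusted p = 0.000494, adjusted p = 0.712 with an estimated correlation). That call was lost with normexp background (0.153), quantile normalization (0.709) and cyclic loess (0.572), and with fry (0.0617). Markers of cardiac and smooth muscle, cells that such cultures can contain, moved with these groups, with 15 of 23 lower, 0 higher and 8 not past (17 lower over the list alone), Tnni3 at -2.42 ± 0.18 and Mybpc3 at -1.99 ± 0.25. Their median lay -0.53 from all genes (camera adjusted p = 0.022, adjusted p = 0.478 with an estimated correlation), but -0.07 with no filter on dim probes, where the call was lost (adjusted p = 0.056). Of 7 nuclear or regulatory non-coding RNAs 3 were lower, 0 higher and 4 not past, also over the list alone (camera adjusted p = 0.86).

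In all, 8301 of 14991 genes passed between GFP IP and input in limma, 2726 higher and 5575 lower, and 2001 and 3862 of them differed at least 2-fold. The split depended on the scaling, because the median gene lay at -0.52 with the 75th percentile. It was 3699 higher and 3638 lower after cyclic loess (median gene shifted by 0.41), 3559 and 1862 with the median of all probes (0.57) and 6950 and 422 with spike-in controls (1.23), and quantile normalization shifted the median gene by 0.27. With spike-in scaling the medians of the oxidative phosphorylation, mitochondrial ribosomal, cytosolic ribosomal and cardiac and smooth muscle lists lay above 0, at 0.11, 0.37, 0.09 and 0.17. The count was 9342 with the slide as a block and 8583 within slide 1, where the spread rests on the input arrays. Slide 2 held 1 GFP and 1 PABP1 array and gave no test. Without input replicate 1 the count was 4186, and without input replicate 2 it was 4855. Relative to all genes, the list medians with the slide as a block and within slide 1 were 1.26 and 1.21 for Polycomb and 0.77 and 0.81 for cytoplasmic RNA-binding proteins. They were -0.65 and -0.73 for oxidative phosphorylation, and 1.35 and 1.28 for the reported DAZL targets.

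**Figure D2:**
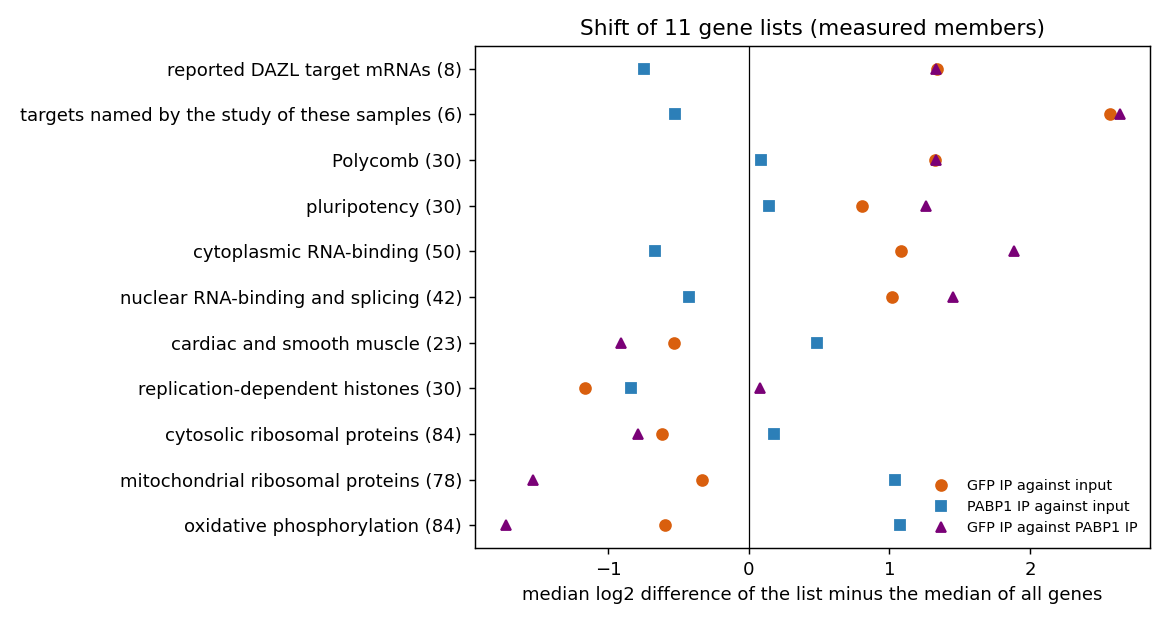
Each symbol is the median log2 difference of a gene list minus the median of all 14991 genes, for GFP IP against input (circles), PABP1 IP against input (squares) and GFP IP against PABP1 IP (triangles), with the number of measured members in parentheses. Oxidative phosphorylation lies at -0.60, 1.07 and -1.73 and Polycomb at 1.33, 0.09 and 1.33; the cytosolic ribosomal list, at -0.62 and -0.79 in the GFP IP comparisons, turns to 0.09 and 0.16 after quantile normalization and to 0.41 against PABP1 IP after cyclic loess, and the mitochondrial ribosomal list at -0.33 against input turns to 0.15 with normexp background.

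The PABP1 IP, a control of the study, was compared with input to show what a general mRNA-binding protein recovers. Most listed mRNAs for the respiratory chain and the mitochondrial ribosome were higher in the PABP1 IP, while the nuclear RNA Malat1 was at least 384-fold lower (adjusted p = 0.000877, n = 2 arrays per group). Of 84 oxidative phosphorylation genes 65 were higher, 2 lower and 17 not past (66 and 2 adjusted over the list alone), with Cox6b1 5.90-fold higher (2.56 ± 0.17 SE) and Atp5l 5.52-fold higher (2.47 ± 0.19). Their median lay 1.07 above all genes (camera adjusted p = 1.07e-08, adjusted p = 0.82 with an estimated correlation). Of 78 mitochondrial ribosomal protein genes 59 were higher, 0 lower and 19 not past (60 over the list alone), with Mrps21 at 2.57 ± 0.16 and Mrpl30 at 2.54 ± 0.15. Their median lay 1.04 above all genes (camera adjusted p = 9.21e-11, adjusted p = 0.82 with an estimated correlation). With the slide as a block and within slide 1 the relative medians were 1.00 and 1.09 for oxidative phosphorylation and 0.93 and 1.01 for the mitochondrial ribosome.

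No other list passed camera in PABP1 IP against input. Of 84 cytosolic ribosomal protein genes 28 were higher, 0 lower and 56 not past (22 over the list alone), at 0.18 above all genes (camera adjusted p = 0.227, adjusted p = 0.893 with an estimated correlation), with Rpl4 at 2.41 ± 0.20 and Rpl22l1 at 2.21 ± 0.20. The list passed with the slide as a block (0.28, adjusted p = 0.0339), within slide 1 (0.50, adjusted p = 4.41e-05) and without PABP1 IP replicate 2 (0.50, adjusted p = 1.5e-05). It also passed with normexp background (3.08e-06), no filter on dim probes (2.54e-05) and every kept probe on its own (0.0179), and its own median turned from 0.31 to -0.39 after cyclic loess. Of 42 nuclear RNA-binding and splicing genes 6 were higher, 17 lower and 19 not past (camera adjusted p = 0.121), with Son 19.7-fold lower (-4.30 ± 0.17, with other probes at -1.24 and -0.36) and Luc7l3 lower (-3.09 ± 0.25). With the slide as a block this list lay -0.70 from all genes (adjusted p = 0.0339), and within slide 1 -0.66 (adjusted p = 0.0484). It also passed with quantile normalization (0.00971), cyclic loess (0.0146), every kept probe on its own (0.0339) and the mean of a gene's probes (0.0416). Of 50 cytoplasmic RNA-binding genes 12 were higher, 22 lower and 16 not past (camera adjusted p = 0.172, but 0.0484 within slide 1 and 0.0339 with every kept probe on its own), with Cnot7 higher (3.19 ± 0.15) and the decay helicase gene Ddx6 (-2.82 ± 0.19) and Pum2 (-2.85 ± 0.39, with other probes at 0.24 and -1.16) lower. Spike-in scaling put both RNA-binding lists above 0, at 2.08 and 1.84. Of 30 histone genes 7 were higher, 14 lower and 9 not past (camera adjusted p = 0.234, but 0.0428 with the slide as a block and 0.0471 with spike-in scaling), with H1f5 at -2.97 ± 0.15. Of 30 Polycomb genes 7 were higher, 5 lower and 18 not past (camera adjusted p = 0.799), with Yaf2 at 2.23 ± 0.22 and Jarid2 at -2.03 ± 0.17 (another probe -0.75). Of 30 pluripotency genes 9 were higher and 9 lower (camera adjusted p = 0.859, with the mean at -0.06 and the test downward although the median was 0.27), with Nr5a2 at -2.71 ± 0.16 and Stat3 at -2.20 ± 0.17. Of 22 primordial germ cell genes 8 were higher and 6 lower (camera adjusted p = 0.97), with Ifitm2 at 2.13 ± 0.20 and Ifitm3 at 1.73 ± 0.17. Of 7 nuclear or regulatory non-coding RNAs 1 was higher and 3 lower (camera adjusted p = 0.421, but 0.000768 with spike-in scaling), among them Rmrp at -1.26 ± 0.17. Of 23 cardiac and smooth muscle markers 6 were higher and 2 lower (camera adjusted p = 0.245), with Myl4 at 2.05 ± 0.15 and Myl2 at 1.97 ± 0.17. Spike-in scaling turned Jarid2 to 0.35, Stat3 to 0.17 and Rmrp to 1.11, and Nr5a2, Luc7l3, Ddx6 and Pum2 lost their calls (adjusted p = 0.174, 0.066, 0.147 and 0.289). With fry, which does not compare a list with other genes, the nuclear and cytoplasmic RNA-binding lists (0.0116), Polycomb (0.0214), cardiac and smooth muscle (0.0397) and the reported DAZL targets (0.0281) passed.

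Against input, Dazl was 3.50-fold lower in the PABP1 IP (-1.81 ± 0.27, adjusted p = 0.0039, with another probe at -0.73). Of the 8 reported DAZL targets 4 were lower, 1 higher and 3 not past, as over the list alone (camera adjusted p = 0.245), with Tex14 (-2.01 ± 0.16) and Sdad1 (-1.69 ± 0.31, with another probe at -0.72) lower and Tbpl1 (1.55 ± 0.16, with other probes at 3.84 and 0.94) higher. These directions depend on the scaling. With spike-in controls Dazl, Tex14 and Sdad1 turned to 0.57, 0.36 and 0.69, and Suz12, Casp2 and Sall4, given next, to 1.40, 1.58 and 1.64. Of the 6 mRNAs taken to be targets of the study 3 were lower, 0 higher and 3 not past (3 lower and 1 higher over the list alone, camera adjusted p = 0.51), which may not be independent evidence. Suz12 (-0.97 ± 0.25, adjusted p = 0.0222) had adjusted p = 0.0983 and 0.0962 without input replicates 1 and 2 and 0.0535 without PABP1 IP replicate 1. Casp2 (-0.79 ± 0.16, adjusted p = 0.0101) had 0.0608 and 0.0769 without the input replicates. Sall4 (-0.73 ± 0.21, adjusted p = 0.0341) had 0.157, 0.112 and 0.121 without input replicates 1 and 2 and PABP1 IP replicate 2, and 0.0718 within slide 1. Another Sall4 probe gave 0.22, and the mean of the Sall4 probes -0.26 (adjusted p = 0.554). With normexp background Suz12, Casp2 and Sall4 also lost their calls (adjusted p = 0.0743, 0.149 and 0.118). They did so with the median of all probes (0.118, 0.0676 and 0.0612) and with no filter on dim probes (0.0696, 0.0598 and 0.111). They also did so with a minimum log2 difference of 0.5 (0.13, 0.139 and 0.308), as did Nanog (0.16), and Sall4 with a replicate block (0.0654). Sox2 (0.30 ± 0.16, adjusted p = 0.163), Casp9 (-0.05 ± 0.23, adjusted p = 0.861) and Tex19.1 (-0.45 ± 0.19, adjusted p = 0.0997) did not pass. Sox2 did pass with normexp background (0.63, adjusted p = 0.0184), and Tex19.1 after quantile normalization (-0.64, adjusted p = 0.0209) and cyclic loess (-0.82, adjusted p = 0.00722). Spike-in scaling turned Tex19.1 to 1.93 and Casp9 to 2.32, and put Sox2 at 2.67 (adjusted p = 6.58e-05). Pou5f1 was 2.83-fold higher (SE 0.29 on the log2 scale, adjusted p = 0.00966; 1.41, adjusted p = 0.0576 without input replicate 1, and 0.79, adjusted p = 0.0776 after quantile normalization), as was Nanog (0.76 ± 0.15, adjusted p = 0.0106; adjusted p = 0.0558 and 0.0842 without input replicates 1 and 2, and 0.0636 with no filter on dim probes). Pabpc1 did not pass (-0.13 ± 0.69, adjusted p = 0.887), but gave 0.64 with adjusted p = 0.0279 with the slide as a block.

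Among genes with an official-looking symbol and measured in both groups, the largest increases over input in the PABP1 IP were those of Tm2d1 (4.22 ± 0.15, 18.6-fold) and Tmem126a (3.91 ± 0.16, 15.0-fold). Gltp (3.84 ± 0.23), the replication protein gene Rpa3 (3.84 ± 0.43), Tmem38b (3.59 ± 0.17), Ttc32 (3.57 ± 0.23), Pde6d (3.51 ± 0.19) and D5Ertd579e (3.50 ± 0.16) followed, and Mycbp was at least 6.17-fold higher (adjusted p = 0.000877). Cenpa (3.51 ± 0.83, adjusted p = 0.0179) gave 2.87 and 2.82 (adjusted p = 0.0851 and 0.0777) without input replicate 1 and PABP1 IP replicate 2. Below input were Rif1 (-6.16 ± 0.41, 71.7-fold), Tpr (-5.99 ± 0.38), Golgb1 (-5.78 ± 0.79), the progranulin gene Grn (-5.68 ± 0.43), Syt10 (-5.60 ± 0.79) and Nol8 (-5.34 ± 0.39). Other probes gave smaller values for Rif1 (-1.25), Tpr (-1.76), Grn (-0.59), Malat1 (-5.46 and -4.14) and Mycbp (1.56 and 1.81). The other Golgb1 probes gave -2.26 and -6.29. Gdap10 was at least 44.2-fold lower, the kinase gene Rock1 at least 32.8-fold lower, and Xntrpc at least 35.1-fold lower (adjusted p = 0.000877, 0.00128 and 0.000916), though the Xntrpc probe well above background on all 6 arrays gave -0.07 (adjusted p = 0.783). In all, 8076 genes passed in limma, 4545 higher and 3531 lower, of which 3347 and 2484 differed at least 2-fold. With spike-in scaling, which shifted the median gene by 2.38, 13354 were higher and 227 lower; the shift was -0.15 after cyclic loess, 0.15 with the median of all probes, -0.24 with normexp background, 0.12 with the slide as a block and 0.13 within slide 1. The count was 9452 with the slide as a block, 8688 within slide 1, and 5111 and 5042 without input replicates 1 and 2.

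The GFP IP was also compared with the PABP1 IP, that of a general mRNA-binding protein. A difference here can come from recovery in the GFP IP or from depletion in the PABP1 IP. Dazl, the mRNA of the tagged protein, had the largest difference, 48.1-fold higher in the GFP IP (log2 difference 5.59 ± 0.27 SE, n = 2 arrays per group, adjusted p = 0.00046), followed by the transcription factor gene Zfx (4.57 ± 0.17), Rif1 (4.38 ± 0.41), Rbm47 (4.24 ± 0.16), Klhl28 (4.12 ± 0.19), Dcaf12l1 (4.09 ± 0.21) and Otud4 (4.02 ± 0.18) among genes with an official-looking symbol and measured in both groups. Malat1 was at least 11.5-fold higher, Thoc2 at least 9.05-fold and Kdm7a at least 8.38-fold (adjusted p = 0.00113, 0.000992 and 0.0012). Against input, however, the GFP IP lay at -1.79 for Rif1, -5.07 for Malat1 and 0.04 for Kdm7a. The PABP1 IP lay at -6.16 from input for Rif1. The GFP IP lay above input for Dazl (3.78), Zfx (1.72), Rbm47 (2.27) and Otud4 (2.37). Lower in the GFP IP were Tyrobp (-4.40 ± 0.24, 21.2-fold), Npb (-3.97 ± 0.15), Tmem126a (-3.95 ± 0.16), Plac8 (-3.82 ± 0.39), Tm4sf5 (-3.75 ± 0.19), Ctla2b (-3.69 ± 0.64), Gng13 (-3.65 ± 0.23) and Saxo2 (-3.62 ± 0.21). Skap1 was at least 3.04-fold and the histone gene H2ac8 at least 6.17-fold lower (adjusted p = 0.00211 and 0.000787). Other probes gave smaller values for Dazl (3.17), Rbm47 (3.12), Zfx (0.06), Rif1 (2.31), Otud4 (1.10 and 3.78), Malat1 (1.36 and 0.27) and Kdm7a (1.93).

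Tex19.1 (3.67 ± 0.19, 12.8-fold) and Sdad1 (3.63 ± 0.31) stood well above the PABP1 IP, and Tex14 was higher at 0.75 ± 0.16 (adjusted p = 0.0104). The Tex14 call was lost with normexp background (0.34, adjusted p = 0.0963) with no filter on dim probes (adjusted p = 0.0603) and with a minimum log2 difference of 0.5 (adjusted p = 0.157), and spike-in scaling turned it to -0.40. Of the 8 reported DAZL targets 5 were higher, 0 lower and 3 not past (5 and 1 over the list alone), with the median 1.33 above all genes (camera adjusted p = 0.00529, adjusted p = 0.269 with an estimated correlation). All 6 mRNAs taken to be targets of the study were higher, also over the list alone, which may not be independent evidence (camera adjusted p = 0.000115, adjusted p = 0.227 with an estimated correlation). Suz12 gave 3.05 ± 0.25, Sall4 2.75 ± 0.21, Casp2 2.24 ± 0.16, Sox2 1.81 ± 0.16 and Casp9 1.68 ± 0.23, and other probes of Sall4, Sdad1 and Suz12 gave -0.41, -0.73 and 2.23. With spike-in scaling Casp9 lost its call (adjusted p = 0.0834). Pou5f1 was lower in the GFP IP (-2.02 ± 0.29, adjusted p = 0.00273; -0.84, adjusted p = 0.0594 after cyclic loess). Nanog was higher (0.65 ± 0.15, adjusted p = 0.0151), with adjusted p = 0.0672 and 0.0527 without GFP IP replicate 1 and PABP1 IP replicate 2. It had 0.0795 within slide 1, 0.0837 with no filter on dim probes and 0.291 with a minimum log2 difference of 0.5, and spike-in scaling turned it to -0.50. Pabpc1 did not pass (-0.74 ± 0.69, adjusted p = 0.38), but did with the slide as a block (adjusted p = 0.00951) and with the crossed replicate block (adjusted p = 0.00781).

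Genes for cytoplasmic RNA-binding proteins lay 1.89 above all genes in the GFP IP against the PABP1 IP, with 32 of 50 higher, 9 lower and 9 not past (32 and 11 adjusted over the list alone). Cpeb1 (3.62 ± 0.27) and Elavl2 (3.26 ± 0.17), regulators of mRNA stability and translation, were among them (camera adjusted p = 3.84e-06, adjusted p = 0.208 with an estimated correlation). Nuclear RNA-binding and splicing genes lay 1.45 above all genes, with 21 of 42 higher, 4 lower and 17 not past (19 and 4 over the list alone), Sf3b1 at 3.56 ± 0.20 (another probe 1.16) and Son at 2.97 ± 0.17 (other probes 0.98 and 1.35) (camera adjusted p = 1.63e-05, adjusted p = 0.227 with an estimated correlation). Against input, the GFP IP lay at 1.04 for Sf3b1 and at -1.33 for Son. Polycomb genes lay 1.33 above, with 14 of 30 higher, 5 lower and 11 not past, as over the list alone (camera adjusted p = 0.0029, adjusted p = 0.227 with an estimated correlation). Jarid2 (3.14 ± 0.17) and Mtf2 (2.97 ± 0.23) were higher and Pcgf1 (-2.77 ± 0.19) lower. Pluripotency genes lay 1.26 above, with 15 of 30 higher, 8 lower and 7 not past, as over the list alone (camera adjusted p = 0.00476, adjusted p = 0.448 with an estimated correlation), and Klf5 at 3.13 ± 0.17. Of 22 primordial germ cell genes 9 were higher and 9 lower (camera adjusted p = 0.23, but 0.0183 with spike-in scaling and 0.0402 with no filter on dim probes), with Kit at 3.63 ± 0.24 and Ifitm2 at -3.31 ± 0.20. Of 7 nuclear or regulatory non-coding RNAs 3 were higher and 1 lower (camera adjusted p = 0.23, but 0.0371 with spike-in scaling). With spike-in scaling the medians of the nuclear RNA-binding, Polycomb, pluripotency and reported DAZL target lists lay below 0, at -0.31, -0.43, -0.50 and -0.43, and that of the cytoplasmic RNA-binding list at 0.13.

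Oxidative phosphorylation genes lay -1.73 from all genes in the GFP IP against the PABP1 IP, with 79 of 84 lower, 0 higher and 5 not past (80 over the list alone), Ndufa3 at -3.52 ± 0.20 (another probe -2.21) and Atp5l at -3.48 ± 0.19 (camera adjusted p = 3.77e-11, adjusted p = 0.438 with an estimated correlation). Mitochondrial ribosomal protein genes lay -1.53 from all genes, with 72 of 78 lower, 2 higher and 4 not past, as over the list alone (camera adjusted p = 1.85e-10, adjusted p = 0.448 with an estimated correlation). Mrps21 (-3.26 ± 0.16) and Mrpl52 (-3.05 ± 0.25) were examples. Cytosolic ribosomal protein genes lay -0.79 from all genes, but 0.16 after quantile normalization and 0.41 after cyclic loess, with 49 of 84 lower, 0 higher and 35 not past, as over the list alone, Rpl29 at -3.14 ± 0.37 and Rpl22l1 at -2.80 ± 0.20. The test of that list gave camera adjusted p = 3.07e-05, adjusted p = 0.663 with an estimated correlation adjusted p = 0.808 after cyclic loess and adjusted p = 0.285 after quantile normalization. Cardiac and smooth muscle markers moved with these groups at -0.90 from all genes, with 20 of 23 lower, 0 higher and 3 not past, as over the list alone, Myl2 at -3.08 ± 0.17 and Myl4 at -3.01 ± 0.15 (camera adjusted p = 0.00292, adjusted p = 0.368 with an estimated correlation). Of 30 histone genes 13 were lower, 3 higher and 14 not past (camera adjusted p = 0.283, with the test downward although the median lay 0.08 above all genes, and 0.0074 with fry), with H2bc4 at -2.53 ± 0.20. Within slide 1 the relative medians were -1.92 for oxidative phosphorylation, 1.92 for cytoplasmic RNA-binding proteins and 1.17 for Polycomb. With the slide as a block they were -1.73, 1.89 and 1.33. These cannot differ from the values over all arrays, since each slide held both IPs in equal number.

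In all, 9581 genes passed between GFP IP and PABP1 IP in limma, 3276 higher and 6305 lower, of which 2511 and 5015 differed at least 2-fold. With the slide as a block 11581 passed, and within slide 1, where each IP has 1 array and the spread rests on the input arrays, 9840. The split was 4001 higher and 4927 lower after quantile normalization (median gene shifted by 0.34), 4631 and 4113 after cyclic loess (0.55), 3833 and 4122 with the median of all probes (0.42) and 1234 and 10754 with spike-in controls (-1.15), and normexp background shifted the median gene by 0.25.

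Dazl, Tex19.1, Suz12, Sall4, Sox2, Casp2, Casp9 and Nanog were among 1742 genes higher in the GFP IP than in both input and PABP1 IP, 1223 of them at least 2-fold in both. Independent lists of the same sizes would share 596, and simulated unchanged groups shared 0.02 on average (100.4 at an unadjusted p below 0.05, against 1921 observed). No gene changed in the simulation, so an adjusted overlap near 0 was fixed in advance. It cannot show what shared arrays add where many genes differ. Both comparisons use the GFP arrays, so part of the excess over independent lists may come from these. Of the 1742 genes, 1716 remained with the slide as a block, 1515 within slide 1 (1 array per IP, so the spread rests on the input arrays) and 860 with spike-in scaling, and the count was 1151 without input replicate 1. Another 1534 genes were higher in the GFP IP than in the PABP1 IP but not higher than in input, and 1311 of these were lower in the PABP1 IP than in input. In the other direction 3464 genes were lower in the GFP IP than in both controls, against 2345 for independent lists.

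Against their shared input, the 2 IPs had 1158 genes higher in both (826 for independent lists) and 1928 lower in both (1313), with 0 of either on average in simulated unchanged groups. The GFP IP was higher and the PABP1 IP lower for 519 genes (642 for independent lists), and the reverse held for 1308 (1690). Across genes the differences from input correlated at 0.333, below the 0.501 that the shared input arrays gave in simulated unchanged groups, while their covariance was 0.529 against a simulated 0.0580. The simulation took the arrays as independent and held no slide difference, although both input arrays lie on slide 1 and each IP has 1 array on slide 2. It also held no changed gene, so its 0 shared genes were fixed in advance. With the slide as a block the correlation was 0.276 and the covariance 0.401, with 1331 genes higher in both (1100 for independent lists) and 2225 lower in both (1676). Within slide 1 they were 0.236 and 0.354, with 1049 higher in both (926) and 1864 lower in both (1403). Part of the overlap may come from the slide and from the shared input arrays.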

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

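The median of all probes, the spike-in controls, the fit within slide 1, the crossed replicate block and the slide block with an estimated correlation were chosen only after the results were seen; the others were planned. Of the comparisons of 191 named gene results with their alternatives, 4447 kept direction and side of the threshold, 75 fell short of it, 9 newly passed and 18 reversed. For the lists, 1718 kept both, 65 fell short, 85 newly passed and 4 reversed. Leaving out saturated probes removed no probe, so its 191 gene and 72 list agreements were fixed in advance. Every kept probe on its own was compared for 118 gene results only, all of which agreed. Genes with several kept probes were skipped there, so that setting does not show whether their probes differ. Many named genes were chosen for large differences past the threshold, so their stability does not extend to all calls. Of all 8301 genes past the threshold in GFP IP against input, 97.0% passed in the same direction with the slide block and 76.5% with cyclic loess. The share was 55.3% with the median of all probes and 37.9% with spike-in scaling. Unless a reason is given, the cause was not tested. With spike-in scaling, which shifts every gene alike, PABP1 IP against input reversed for Tex14 (0.36), Dazl (0.57), Sdad1 (0.69), Suz12 (1.40), Casp2 (1.58), Sall4 (1.64), Stat3 (0.17), Jarid2 (0.35), Rmrp (1.11), Nes (0.42), Ncam1 (0.54), Pabpc1 (2.24), Tex19.1 (1.93) and Casp9 (2.32), and GFP IP against PABP1 IP for Tex14 (-0.40) and Nanog (-0.50). Pabpc1 in PABP1 IP against input reversed to 0.64 with the slide block, and Ccdc43 in GFP IP against input to -0.49 where probes had to be well above background on all 6 arrays, which selects another probe. Among lists, translation factors reversed in GFP IP against input with normexp background (0.43). In GFP IP against PABP1 IP the cytosolic ribosomal list reversed with cyclic loess (0.41). There the apoptosis and heat shock lists reversed with fry, which does not compare a list with other genes. The apoptosis and heat shock medians themselves were -0.36 and -0.34, but relative to all genes they lay at 0.25 and 0.27. Of the counts, GFP IP against input gave 3638 lower after cyclic loess, 14962 past and 12585 lower with no filter on dim probes, 4356 higher with every kept probe on its own, 5421 past and 1862 lower with the median of all probes, and 6950 higher and 422 lower with spike-in scaling. PABP1 IP against input gave 13581 past, 13354 higher and 227 lower with spike-in scaling. GFP IP against PABP1 IP gave 4113 lower after cyclic loess, 4122 lower with the median of all probes, 5143 higher with every kept probe on its own, and 1234 higher and 10754 lower with spike-in scaling. A minimum log2 difference of 0.5 gave 4574 past, 1675 higher and 2899 lower in GFP IP against input, and 5020, 2841 and 2179 in PABP1 IP against input. The genes higher than both controls numbered 2705 with every kept probe on its own, 1056 with that minimum and 1083 with spike-in scaling. Leaving out each array in turn, with the lone array assumed to vary like the other groups, gave 4186 to 8455 past, 1637 to 2742 higher and 2549 to 5713 lower in GFP IP against input. The ranges were 5042 to 7988, 2846 to 4531 and 2154 to 3457 in PABP1 IP against input and 7937 to 9096, 2806 to 2973 and 5131 to 6123 in GFP IP against PABP1 IP. Genes higher than both controls numbered 1151 to 1692; these and the counts of GFP IP against input were lowest without input replicate 1, and those of GFP IP against PABP1 IP without PABP1 IP replicate 1. The authors' values were not run as an alternative. Signal over background limits the folds given as at least a value.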

Other observations

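The tests of the slide, of the shared starting culture, and of signal level for the Polycomb, cytoplasmic RNA-binding and reported DAZL target lists were chosen only after the results were seen. Stress and cell cycle genes were split within their lists. Of 28 heat shock and stress genes 9 were higher and 10 lower in the GFP IP than in input (camera adjusted p = 0.177, with the median at -0.09 and the mean at 0.17, but 0.0355 with normexp background and 0.000865 with no filter on dim probes), with the immediate early phosphatase gene Dusp1 at 2.79 ± 0.30 SE and Hmox1 at 2.29 ± 0.18. In the PABP1 IP 13 were higher and 4 lower than input (adjusted p = 0.251, but 0.00217 with no filter), with Atf4 at 2.28 ± 0.30 and Xbp1 at 2.10 ± 0.19. Against the PABP1 IP 4 were higher and 10 lower in the GFP IP (adjusted p = 0.973), with Hspb1 at -2.19 ± 0.19 and Hmox1 at 2.02 ± 0.18. Of 42 cell cycle genes 12 were higher and 12 lower in the GFP IP than in input (camera adjusted p = 0.0779, adjusted p = 0.427 with an estimated correlation), with Ccnd1 at 2.08 ± 0.27 and Mki67 at -2.08 ± 0.22. That list passed without GFP IP replicate 2 (0.0373), with normexp background (0.00593), cyclic loess (0.0297), no filter (8.47e-05), every kept probe on its own (0.0401), the mean of a gene's probes (0.0305), the median of all probes (0.0495) and spike-in scaling (0.0374). In the PABP1 IP 10 were higher and 13 lower than input (adjusted p = 0.394), with Cdk4 at 2.26 ± 0.22 and Mki67 at -2.38 ± 0.22 (another Mki67 probe gave -3.87, and -2.69 in the GFP IP). With spike-in scaling the Mki67 calls were lost against input in the GFP IP (-0.85, adjusted p = 0.0625) and in the PABP1 IP (adjusted p = 0.999). In the GFP IP 14 were higher and 11 lower than in the PABP1 IP, with Ccnd1 at 2.68 ± 0.27 (adjusted p = 0.039, adjusted p = 0.269 with an estimated correlation; 0.0703 and 0.0537 without GFP IP replicate 1 and PABP1 IP replicate 1, 0.223 with spike-in scaling and 0.077 with probes well above background on all 6 arrays). Of 37 apoptosis genes 13 were higher and 11 lower in the GFP IP than in input (adjusted p = 0.117, with the median at -0.13 and the mean at 0.18, but 0.00164 with no filter), with Pmaip1 at 2.96 ± 0.19. In the PABP1 IP 14 were higher and 8 lower than input (adjusted p = 0.395, but 0.00692 with no filter), with Bax at 2.29 ± 0.18. In the GFP IP 12 were higher and 15 lower than in the PABP1 IP (adjusted p = 0.574), with Xiap at 2.86 ± 0.22 (another probe 3.53) and Bax at -2.80 ± 0.18. Of 38 translation factor genes 9 were higher and 18 lower in the GFP IP than in input (adjusted p = 0.875, but upward with 0.0355 with normexp background), with Paip1 at 1.76 ± 0.14 and Eif5b at -3.09 ± 0.47 (other Eif5b probes -0.79, -1.23, -2.54 and -3.11, other Paip1 probes 3.79 and 1.13). In the PABP1 IP 14 were higher and 7 lower than input (adjusted p = 0.394, but 0.00119 with normexp background and 0.00481 with no filter), with Paip2 at 2.01 ± 0.16 and Eif5b at -4.80 ± 0.47 (other probes -1.41, -1.30, -2.95 and -5.56). In the GFP IP 8 were higher and 23 lower than in the PABP1 IP (adjusted p = 0.23), with Eif3f at -2.39 ± 0.16. Of 16 meiosis genes 3 were higher and 7 lower in the GFP IP than in input (adjusted p = 0.806), with the cohesin genes Rec8 at -1.83 ± 0.25 and Stag3 at -1.66 ± 0.20, whose calls were lost with spike-in scaling (-0.60, adjusted p = 0.0962 and -0.43, adjusted p = 0.178). In the PABP1 IP 3 were higher and 5 lower than input (adjusted p = 0.245), with Syce2 at 2.18 ± 0.17. In the GFP IP 5 were higher and 5 lower than in the PABP1 IP (adjusted p = 0.293), with the median at 0.18 and the mean at -0.22. With fry, which does not compare a list with other genes, meiosis passed in GFP IP against input (0.0394), heat shock (0.0293), apoptosis (0.0157) and translation factors (0.0293) in PABP1 IP against input, and translation factors (0.00487), apoptosis (0.0204) and heat shock (0.023) in GFP IP against PABP1 IP.

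Apart from cardiac and smooth muscle, lists of secreted and lineage marker genes did not pass in the GFP IP against input. Of 44 secreted and extracellular matrix genes 2 were higher and 21 lower (adjusted p = 0.126), with Fbln2 at -2.74 ± 0.25; the list passed without GFP IP replicate 2 (adjusted p = 0.0294), without input replicate 1 (0.0239) and with every kept probe on its own (0.00686). Of 16 fibroblast and feeder markers 0 were higher and 10 lower (camera adjusted p = 0.0535, adjusted p = 0.699 with an estimated correlation), with Thy1 at -1.74 ± 0.24. This list lies near the threshold, and it passed without GFP IP replicate 2 (adjusted p = 0.0154), without input replicate 1 (0.00838), with a replicate block (0.0142) and with trend and robust (0.038). It also passed with normexp background (0.0465), the median of kept probes (0.0479), the median of all probes (0.0274), spike-in scaling (0.0353), a floor at the lowest detected signal (0.0482), every kept probe on its own (0.00665) and the mean of a gene's probes (0.0371). Visceral endoderm markers were 2 higher and 5 lower of 19 (adjusted p = 0.806, the test downward although the median lay 0.02 above all genes, Apoe at -2.28 ± 0.28), trophoblast markers 1 and 4 of 8 (adjusted p = 0.329, Krt8 at -1.63 ± 0.19), endothelial and blood markers 1 and 4 of 15 (adjusted p = 0.842, Pecam1 at 2.28 ± 0.19), and neural markers 5 and 2 of 20 (adjusted p = 0.132, Nes at -2.22 ± 0.30 and Tubb3 at 1.77 ± 0.28). In the PABP1 IP against input the counts were 9 higher and 8 lower for matrix genes (adjusted p = 0.6, median -0.07 and mean 0.00), 5 and 2 for fibroblast (0.421), 7 and 3 for visceral endoderm (0.395), 3 and 0 for trophoblast (0.6), 3 and 3 for endothelial and blood (0.833) and 5 and 5 for neural markers (0.642, with Nes at -1.96 ± 0.30 and Ncam1 at -1.84 ± 0.18, whose other probes gave 0.44, 0.78, -0.41, -0.95 and -3.35). In the GFP IP against the PABP1 IP they were 5 higher and 22 lower (0.415, Timp1 at -2.76 ± 0.17), 1 and 13 (0.0563, S100a4 at -3.02 ± 0.21), 1 and 8 (0.262, Apoc2 at -2.72 ± 0.18), 1 and 5 (0.283, Krt19 at -2.39 ± 0.24), 2 and 8 (0.52, Pecam1 at 3.16 ± 0.19) and 6 and 4 (0.23), in the same order. The fibroblast list, again near the threshold, passed there without GFP IP replicate 2 (adjusted p = 0.0177), PABP1 IP replicate 1 (0.0312) or either input replicate (0.0408), with a replicate block (0.025), with trend and robust (0.0461) and with only the groups compared (0.0408). It also passed with normexp background (0.0312), quantile normalization (0.0444), cyclic loess (0.0398), no filter (0.0154), the median of all probes (0.0175), every kept probe on its own (0.0386) and the mean of a gene's probes (0.0439). In camera with an estimated correlation it did not pass (adjusted p = 0.663). With fry it passed (0.0172), as did matrix (0.0317), visceral endoderm (0.0102), neural (0.0167), endothelial and blood (0.0204) and trophoblast (0.00102) genes, and the trophoblast list did against input in the GFP IP (0.00433) and the PABP1 IP (0.0421). With spike-in scaling Thy1, Krt8 and Nes lost their calls in GFP IP against input (adjusted p = 0.191, 0.139 and 0.0543), and in PABP1 IP against input Nes and Ncam1 turned to 0.42 and 0.54.

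Replicate differences of the 2 IPs mirrored each other: across genes, replicate 1 minus replicate 2 of the GFP IP correlated with that of the PABP1 IP at -0.651. An intensity-dependent scale difference between arrays is argued against, since the correlation of slide 2 minus slide 1 was still 0.649 after cyclic loess. Taken as slide 2 minus slide 1, the same differences correlate at 0.651, which only restates the pattern and does not test a slide or scan difference, with cytosolic ribosomal protein genes at -0.53 and heat shock genes at 0.21 on that axis, against -0.09 for all genes. A slide difference and a shared starting culture with crossed replicate numbers cannot be told apart, because each such pair is also a slide. No biological explanation was tested.

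Most respiratory chain (65 of 84) and mitochondrial ribosome (59 of 78) mRNAs were higher in the PABP1 IP than in input, though neither list passed with an estimated correlation (adjusted p = 0.82). Signal level is argued against as the whole cause, since the medians of the lists, 1.21 and 1.17, lay at percentile 100 of 10000 random lists matched on mean signal, whose own medians averaged near 0.53 and 0.34. The slide is argued against too, since within slide 1 the relative medians kept at least 0.976 of their size. Binding by PABP1 is a candidate explanation; transcript length, poly(A) tail length and unspecific recovery on the beads were not tested here, the last because no mock IP is among the samples.

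Polycomb, cytoplasmic RNA-binding and reported DAZL target lists passed upward in the GFP IP against both controls with a fixed small correlation, but not with an estimated one (adjusted p = 0.138, 0.138 and 0.427 against input, 0.227, 0.208 and 0.269 against PABP1 IP), and with spike-in scaling the medians against PABP1 IP were -0.43, 0.13 and -0.43. For Polycomb and cytoplasmic RNA-binding genes the estimated correlations, -0.021 and -0.0040, lay below the preset 0.01. A higher correlation between genes is therefore not why these 2 lists lost their calls. Signal level is argued against for Polycomb and cytoplasmic RNA-binding genes, whose medians lay at percentile 99.98 or higher of matched random lists in both comparisons. For the reported DAZL targets the lower percentile was 97.68, too close to the limit set for the test, and signal level cannot be told apart from a list effect. The slide is argued against for the Polycomb and cytoplasmic RNA-binding lists, whose relative medians within slide 1, on 1 array per IP, kept at least 0.749 of their size, and for the reported DAZL targets, which kept at least 0.960. Binding by DAZL may contribute, but unspecific recovery with the GFP antibody and transcript features were not tested, so this stays a hypothesis. Nor was it tested whether the cell types of the culture that carry the tagged protein differ from the rest.

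A hypothesis set before its test was that mRNAs with AU-rich elements follow the GFP IP. The test used a list of 27 textbook mRNAs of this kind, 18 of them measured. Members whose values had already been seen were left out, so the list may lack mRNAs with large differences. Of the measured ones, 7 were higher and 3 lower in the GFP IP than in input, with a median of 0.16 at percentile 97.72 of matched random lists. Against the PABP1 IP 6 were higher and 5 lower, with a median of -0.01 at percentile 94.59. For this reduced list the hypothesis therefore did not hold in both comparisons. The percentile against input lay close to the limit set for the test.

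The bright spike-in controls, which are added with the label and carry no cell RNA, were read from the brightest spike-in probes of each array. On the log2 scale they lay 9.66 above the 75th percentile in input, 7.29 in the PABP1 IP and 8.43 in the GFP IP. Saturation was counted without control spots. Whether these controls were saturated, which would distort the spike-in scaling, was not tested. In the authors' table, Dazl has 49.6 in input, 24.6 in the PABP1 IP and 362 in the GFP IP (5.79, 4.05 and 32.5 in another entry), Tex19.1 has 114, 119 and 1438, and Sox2 has 17.9, 41.3 and 249. Sall4 has 18.998, 11.9 and 121 in an entry and 40.9, 27.2 and 15.8 in another, and Suz12 has 11.9, 23.5 and 269 in an entry and 10.9, 3.31 and 36.5 in another. Across 7312 genes, each column of group means correlated best with its own group's arrays, at 0.888 for input, 0.919 for the PABP1 IP and 0.916 for the GFP IP. The log2 differences of that table correlated with those of the scanner values at 0.741 for GFP IP against input, 0.684 for PABP1 IP against input and 0.902 for GFP IP against PABP1 IP across genes, and 78.8%, 77.5% and 88.0% of genes had the same sign.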
